A study of Mus musculus with 2 samples.

How the data were processed

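Mouse iPSCs were profiled in 2 samples, 1 hybridized and 1 live, grouped by the sample type given in the labels. Per the labels' protocols, RNA was extracted with Trizol LS, amplified with the NuGEN Ovation system and labelled with biotin as cDNA. The platform table identifies an Affymetrix mouse expression array, whose probes lie mostly toward the 3' end of transcripts. Per the submitters' processing notes the tools were GCRMA and affy; their versions and order are not given in the sources used here. GCRMA corrects each probe for background that depends on its base composition, normalizes arrays to each other and summarises the probes of a probe set.

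The authors deposited 1 value per probe set and array, with 2 decimals, taken here as log2 GCRMA values. The log base is not stated in the file; it was inferred from the method and from the range of 1.02 to 14.24. Which arrays were normalized together is not given in the sources used here. No detection calls were used here, so the level of 5 is a set limit and not a test of presence, and values near the lower end have no order. The table holds 22690 probe sets, of which 64 are controls. Of the other 22626, 20380 have 1 gene in the platform table, 691 have several and 1555 are unnamed here. These last groups were left out, which removed the ordinary probe sets of Gapdh. Symbols come from the platform table and were checked through Entrez IDs against RefSeq gene names (assembly GRCm38.p6), where 12369 of 12393 genes matched. The files name no genome build, so no coordinates are given.

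For each gene the probe set with the highest mean of the 2 arrays was used, and genes with a mean log2 value of 5 or more were compared. The difference is hybridized minus live, and a gene is called 2-fold apart at a difference of at least 1 in size. Because each group has 1 array, no model was fitted and no p-value is given; the arrays compare these 2 preparations, and nothing in the design separates hybridization from any other difference between them. Each of 33 gene lists, of pathways, transcript classes and markers of other cell types, was fixed before the data were examined. For the 28 lists with at least 5 genes at the level, the median difference was placed among 10000 random lists of the same size drawn from the same 20 level bins. A list stands apart outside the central 95% of these, which is a description of 2 arrays and not a test of the conditions. The agreement of the brightest and second brightest probe sets of a gene served as a measure of technical spread within the arrays; it covers no biological or preparation error.

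The genes named were set beforehand: the 10 highest and 10 lowest differences among genes at 5 or more on both arrays, up to 5 genes per direction with the highest value on one array, at 6 or more there and under 4 on the other, the 3 members furthest in its direction of each list standing apart, and 8 fixed genes. The first 2 parts pass over clone and predicted-gene names. Other members of the lists are named as examples, chosen after their values were seen.

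The alternatives were other level limits (4, 7 or none), the mean over a gene's probe sets, probe sets without the suffixes _x_at, _s_at and _a_at, which mark probes shared between genes or families or, for _a_at, between transcripts of the same gene, centring on the median gene, a loess correction on level (span 0.3), quantile normalization of the 2 arrays, fold thresholds of 1.5 and 4, other matching of random lists, the mean in place of the median, and the limit applied to each array. The mean over a gene's probe sets included probe sets under the level. Centring on the hybridization controls, leaving out only _x_at and _s_at, counting only genes repeated on a second probe set, and lists without some members were added after the data were seen. A planned relation with transcript length was not run, since the gene table used here holds no transcript lengths; the lists of long and short mRNAs stand for it. The procedure was tested on simulated data with the real genes' levels and an SD of 0.86, which is the SD of the real differences and so includes any real change. By that choice of SD, 24.3% of 7062 simulated unchanged genes passed 2-fold, close to the 23.8% of real genes. Changes of 3 log2 units were recovered for 98% of 50 genes in each direction and changes of 1.5 for 80% of 50 upward and 72% of 50 downward. Lists of 20 shifted by 1 log2 unit stood apart in 99.5% of 200 cases, against 3% of unshifted lists. The simulated genes were independent with the same SD at every level, whereas the real SD was 1.00 at means from 7 to under 9 and 0.53 from 11. Smaller shifts of lists were not simulated, so these rates do not describe lists with smaller medians. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.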

Results

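Expression was measured in mouse induced pluripotent stem cells (iPSCs), somatic cells returned to a pluripotent state, that had been grown in serum medium with 2i, a pair of kinase inhibitors that holds mouse pluripotent cells in the naive state. RNA from 1 hybridized sample and 1 live sample was amplified, labelled with biotin and measured on 1 array each. The labels do not say what the cells were hybridized with or how they were prepared for it. The comparison addresses how closely the transcript profile read from hybridized cells matches that of live cells. With 1 array per group no test of the difference is possible, no value has a replicate error, and the number of arrays limits the precision. Each difference below is the log2 value of the hybridized sample minus that of the live sample, and describes these 2 arrays. The log2 values had a median of 5.67 in the hybridized sample and 5.73 in the live sample over 22690 probe sets. Of 12393 genes with a probe set of their own, 7262 had a mean log2 value of 5 or more and were compared.

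The pluripotency genes named beforehand differed by less than 2-fold between the 2 arrays. Nanog, a core pluripotency factor, read 13.17 in the hybridized sample and 13.03 in the live sample. Sox2 read 12.76 and 12.77, Zfp42, a marker of naive cells also known as Rex1, 12.37 and 12.23, and Klf4, a reprogramming factor, 11.56 and 11.65. Esrrb, a naive-state nuclear receptor, was lower by 0.40 with 11.70 in the hybridized sample. Its mean over all probe sets was 0.41 higher, but its other probe set had a mean under the level of 5. Pou5f1, which encodes Oct4, was the lowest of these at 10.83 against 11.53, a difference of -0.70 that was measured on a single probe set. Of 21 core pluripotency genes measured at the level, 0 were 2-fold higher and 1 was 2-fold lower, namely Foxd3 at -1.14; centred on the hybridization controls, described below, 6 were 2-fold higher and 0 lower. The median of this list was 0.09 and its mean -0.03, and the median lay at percentile 92.2 of 10000 random lists of the same size and level. The naive list of 21 genes had a median of -0.09 at percentile 49.2, with Gbx2 (-1.78) and Klf2 (9.69 against 10.69) as its members at least 2-fold lower and Dppa3 at 0.98 as its highest; under that centring 5 were 2-fold higher and 0 lower. The primed or formative list of 12 genes had a median of -0.16 at percentile 61.1, with Otx2 at 1.04 on one side and Etv4 at -1.63 and Pou3f1 at -1.62 on the other. As deposited 2 of its genes were 2-fold higher and 4 lower, and centred on the hybridization controls 5 were higher and 0 lower. Its median was 0.055 (percentile 71.1) at a level of 7 and -0.43 (percentile 10.3) when probe sets were averaged.

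Across the 7262 genes the arrays correlated with Pearson r = 0.920 and Spearman rho = 0.926, taken over genes, which are not independent replicates. In all, 612 genes were at least 2-fold higher and 1115 at least 2-fold lower in the hybridized sample, together 23.8% of the genes compared, while 52.7% lay within 1.5-fold. The median gene differed by -0.17 and the SD of the difference over genes was 0.86. Differences narrowed with signal: 36.2% of genes with a mean from 5 to under 7 were at least 2-fold apart, against 6.31% of genes with a mean of 11 or more. The direction of the split depended on the centring. Genes higher in the hybridized sample made up 35.4% of the 2-fold genes as deposited, 49.4% (814 of them against 833 lower) after centring on the median gene, 54.2% (838 against 708) after a loess correction for level, and 91.8% (2310 against 206) after centring on the hybridization controls, which adds 0.80 to every difference. Any single difference between -0.80 and 0 therefore turns positive under this last centring, and a gene list described below as lower is lower relative to other genes of the same level.

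**Figure D1:**
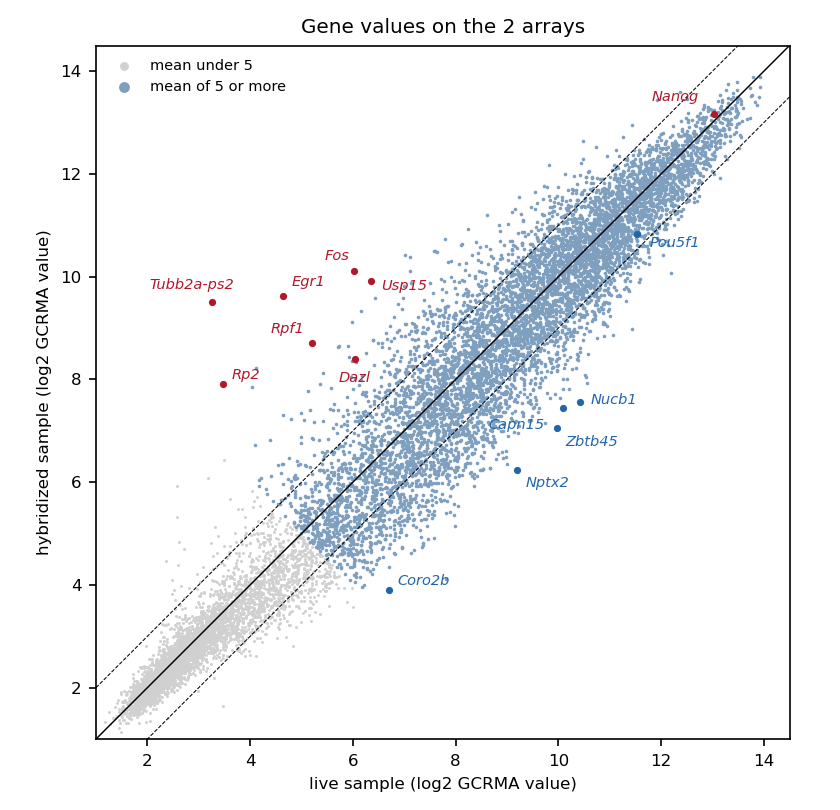
Log2 values of 12393 genes in the live sample (horizontal axis) and the hybridized sample (vertical axis), 1 array each. Each point is a gene, the solid line marks equal values and the dashed lines a 2-fold difference; named points in red were higher and in blue lower in the hybridized sample, and Fos at 10.12 against 6.02 lies far above the upper dashed line.

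Among genes at 5 or more on both arrays, clone and predicted-gene names passed over, the furthest above the live sample was Fos (Entrez 14281), a subunit of the AP-1 transcription factor and an immediate early gene, at 10.12 against 6.02 on its only probe set, a 17.1-fold difference. Next came Usp15, a deubiquitinase (9.91 against 6.35), and Rpf1, a ribosome production factor (8.70 against 5.21). Etv5, an ETS transcription factor downstream of FGF and ERK signalling, was 3.41 higher on its brightest probe set and 0.75 higher on the other. Fdps, an enzyme of the mevalonate pathway, was 3.27 higher, Srr, serine racemase, 3.18, and Nt5c2, a cytosolic nucleotidase, 3.15. Crnkl1, a spliceosome component, was 3.12 higher, Senp6, a SUMO protease, 3.01, and Lpar1, a lysophosphatidic acid receptor, 2.94. In the other direction Nptx2 (Entrez 53324), a neuronal pentraxin, was furthest below at 6.24 against 9.20, a 7.78-fold difference. Zbtb45, a zinc finger protein, differed by -2.91, Nucb1, a calcium-binding protein of the Golgi, by -2.86, and Triobp, an actin-binding protein, by -2.84. Capn15 (-2.66), Stx1a, a SNARE protein (-2.65), Dgkz, a diacylglycerol kinase (-2.63), Atp13a2, a lysosomal ATPase (-2.60), Cbarp (-2.58) and Gtf3c5, a subunit of the RNA polymerase III factor TFIIIC (-2.52), completed the list. These 10 stayed below 0 under each alternative run. Averaged over all probe sets of a gene, the differences were smaller for Rpf1 (1.80), Etv5 (2.08), Fdps (1.56), Srr (1.71), Nt5c2 (1.06), Crnkl1 (1.47), Senp6 (1.69), Lpar1 (near that of Crnkl1), Nptx2 (-1.91), Capn15 (-1.86), Stx1a (-1.76) and Cbarp (-1.98). Rpf1, Fdps, Nt5c2, Crnkl1, Senp6, Nptx2, Stx1a and Cbarp had no second probe set at the level. Their averages therefore include probe sets under it.

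A rule set beforehand took genes low on one array and clearly higher on the other. It took 4 genes at 6 or more in the hybridized sample and under 4 in the live sample. They were Tubb2a-ps2, a tubulin pseudogene that is uncertain because it resembles tubulin transcripts, at 9.51, Rp2 at 7.92, Rin2 at 6.43 and Net1 at 6.09. The second probe set of Rp2 differed by only 0.07. In the live sample 3 genes met the mirrored condition, Coro2b at 6.70, Rnf208 at 6.18 and Dmpk at 6.01. Of the 27 genes named for the size of their difference, 8 had a second probe set at the level, and 6 of these were at least 2-fold apart in the same direction on it. Srr differed by 3.62 there, Capn15 by -2.73, Dgkz by -2.84 and Coro2b by -2.64, while Lpar1 differed by 1.04 and Atp13a2 by -1.24.

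A gene's difference repeated only in part on another probe set. Over 2720 genes with a second probe set at the level, the differences at the brightest and second brightest probe sets correlated with r = 0.390 across genes. The SD of their gap divided by the square root of 2 was 0.73, against an SD of 0.81 for the difference itself. Of 545 genes at least 2-fold apart on the brightest probe set, 197, or 36.1%, were 2-fold apart in the same direction on the second, 417 had the same sign and 23 were 2-fold apart in the opposite direction.

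Genes of the germ line were the only list of 28 to lie above the random lists. Of 10 members measured at the level, 6 were at least 2-fold higher in the hybridized sample, 0 were 2-fold lower, and the median was 1.06 at percentile 99.97. Hormad1, a meiotic chromosome axis protein, read 9.38 against 6.96, Dazl, an RNA-binding protein of germ cells, 8.40 against 6.04, and Stk31 6.04 against 4.17. Sycp3, of the synaptonemal complex, was 1.25 higher, Ddx4, the germ cell RNA helicase Vasa, 1.06 and Piwil2 1.05, whereas Tex19.1 (-0.22) and Stra8 (-0.43) were not higher. The list stayed above the central 95% of random lists in the 12 alternatives that can move its percentile, while the centrings on the median gene and on the hybridization controls shift all genes alike and cannot. Its median was 0.81 at a level of 4 and 0.53 with no limit on level. Averaged over all its probe sets, Dazl was 1.09 higher rather than 2.36, but its other probe set had a mean under the level. A second probe set at the level existed for 1 of the 10 genes, Stk31, and was 1.05 higher. On the same arrays the control probe sets showed a gain of 5' over 3' signal in the hybridized sample, by 2.52 for Actb and 1.81 for Gapdh. For Tfrc it was 0.50, with the 3' probe set also 1.38 higher and the live 5' value under the level at 4.08. The same arrays underlie each other list.

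The unfolded protein and integrated stress response list lay below the random lists. Of 25 members, 8 were at least 2-fold lower and 1 higher, and the median was -0.64 at percentile 0.055, but centred on the hybridization controls 0 were 2-fold lower and 5 higher, with a median of 0.16 at the same percentile. The lowest were Trib3, a pseudokinase induced by ATF4 (-1.54), Shmt2, a mitochondrial enzyme of serine metabolism (-1.48), and Sesn2 (-1.21). Vldlr (-1.19), Chac1 (-1.13), Phgdh (-1.12), Sdf2l1 (-1.08) and Hyou1 (-1.02) were also at least 2-fold lower. Nupr1 was 2-fold higher at 11.66 against 10.66, and the chaperones Hspa5 and Hsp90b1 were each 0.77 higher, so members of the list differed in direction. Without the suffixed probe sets (_x_at, _s_at and _a_at) the median was -0.48 at percentile 2.73, inside the central 95%, and Shmt2 differed by -0.29; with _a_at kept it was -0.40 at percentile 4.4. The second probe sets of Trib3 and Sesn2 differed by -0.83 and -0.20, both under 2-fold, and the mean over the probe sets of Sesn2 by -0.71.

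The other 5 lists below the random lists held genes of protein synthesis, respiration, the secretory route and the cytosol, and their shifts were small. Their medians turned positive, at 0.38 to 0.53 with unchanged percentiles, when centred on the hybridization controls. Only their place relative to other genes is therefore described here. Differences at those controls ran from -1.22 to -0.15, so a common shift does not settle the sign of these lists. As deposited, their shares of 2-fold lower members were no larger than that of all genes, 1115 of 7262. That share is not matched on level, so it does not rule out an excess of lower members. Only 6.31% of genes with a mean of 11 or more were 2-fold apart in either direction. Membrane and secreted proteins alone exceeded all genes under other centrings. They had 8 of 53 lower against 833 of 7262 after median centring, and 4 against 206 with control centring. The 40 ribosomal protein genes had a median of -0.37 at percentile 0.02, with 31 below 0 and none 2-fold apart (1 below 0 and 2 at least 2-fold higher with control centring); Rpsa (-0.86), Rps26 (-0.71) and Rps7 (-0.70) were the lowest. Of 69 nuclear-encoded genes of oxidative phosphorylation, 52 were below 0 and 6 at least 2-fold lower, with a median of -0.33 at percentile 0.12 (2 lower after median centring, and 0 lower and 7 higher with control centring); the lowest were the complex I subunits Ndufb9 (-1.39), Ndufv2 (-1.19) and Ndufs7 (-1.15). Genes of membrane and secreted proteins made at the endoplasmic reticulum had a median of -0.42 at percentile 0.125 over 53 members, 8 of them at least 2-fold lower and 1 higher (4 lower and 10 higher with control centring), led by the tetraspanin Cd151 (-2.04), the integrin Itga3 (-2.02) and the gamma-secretase subunit Ncstn (-1.85). Genes of abundant soluble cytosolic proteins, also 53, had a median of -0.27 at percentile 2.4, with Pgls (-1.38), Tagln2 (-1.08) and Tuba1a (-1.04) lowest. The 43 short mRNAs had a median of -0.40 at percentile 0.20, with Cox8a (-0.95), Dynll1 (-0.83) and Bola2 (-0.81) lowest, and shared 5 genes with the ribosomal protein list and 10 with the respiration list. Without the suffixed probe sets the median was -0.28 at percentile 3.7 for ribosomal proteins, 0 at percentile 34.1 for oxidative phosphorylation and -0.16 at percentile 19.2 for short mRNAs; there Ndufb9 differed by 0.50, Ndufv2 by -0.26, Ndufs7 by -0.04 and Cd151 by -0.58. With only _x_at and _s_at left out, ribosomal proteins (percentile 0.05) and membrane and secreted proteins (0.15) still lay below, whereas oxidative phosphorylation (6.2), cytosolic proteins (3.8) and short mRNAs (4.3) lay inside. The second probe sets of Rps7 (-0.02), Bola2 (0.02) and Ndufs7 (-0.04) showed almost no difference, and that of Ndufb9 was 0.50 higher. Those of Cd151 (-1.87), Itga3 (-1.31), Dynll1 (-0.90), Ndufv2 (-0.74) and Cox8a (-0.72) were lower too. Means over probe sets were smaller for Ndufb9 (-0.40), Ndufv2 (-0.73), Ndufs7 (-0.60), Cd151 (-0.79), Itga3 (-0.97) and Tagln2 (-0.69). For Tagln2 the mean includes a probe set under the level. Against random lists not matched on level, these 5 lists lay at percentiles from 2.99 to 21.7. The respiration list was also inside when probe sets were averaged, and the cytosolic list at levels of 4 and 7 and after loess. About 1.4 of 28 lists would fall outside the central 95% by chance. Of the 7 that did, 6 kept a share of random lists under 0.05 after Benjamini-Hochberg adjustment over the 28, and the cytosolic list did not (0.24). The random lists took genes as independent, while differences of adjacent measured genes correlated with rho = 0.198, so both figures may be too favourable.

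**Figure D2:**
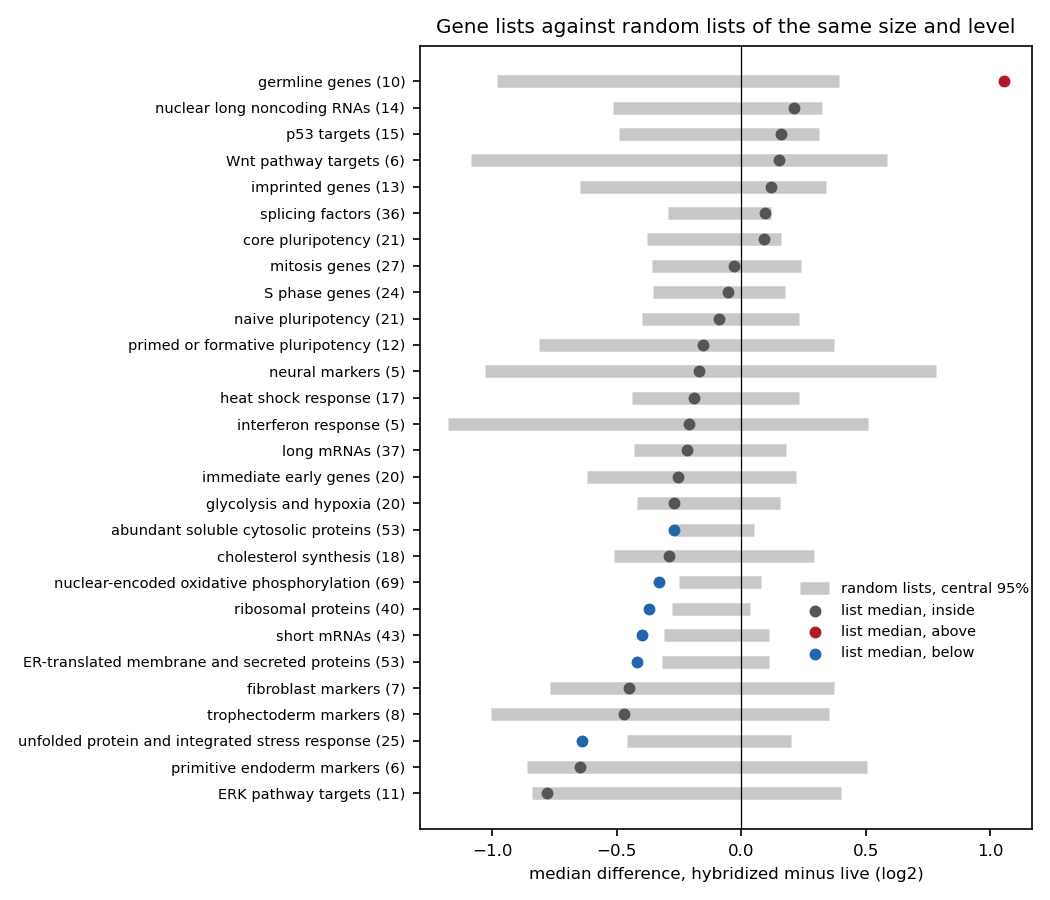
Median log2 difference, hybridized minus live, of 28 gene lists fixed beforehand (points; number of measured genes in parentheses), with the central 95% of 10000 random lists of the same size and level (grey bars). Germline genes lie above their bar at 1.06, 5 lists lie below theirs and cytosolic proteins lie at the lower end of theirs (-0.27); these 6 medians turn positive when centred on the hybridization controls.

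Immediate early genes and the signalling and stress lists other than the unfolded protein and integrated stress response did not stand apart as groups. Among 20 immediate early genes, 4 were at least 2-fold higher and 4 at least 2-fold lower, and the median was -0.26 at percentile 40.4 while the mean was 0.21 at percentile 97.465, just inside the central 95%; centred on the hybridization controls, 6 were higher and 0 lower. Beside Fos, the higher members were Egr1, a zinc finger transcription factor, at 9.62 against 4.65, Gadd45b at 8.48 against 6.80, with -0.13 on its second probe set, and Gadd45a at 10.56 against 9.20. Egr1, measured on 1 probe set, was chosen after its values were seen. The lower members were Jun at 4.96 against 6.46, Nr4a1 at 7.94 against 9.44, Myc at 6.37 against 7.37 and Jund, which differed by -1.36. The 11 ERK pathway targets had a median of -0.78 at percentile 3.96 and a mean of 0.17, since Egr1 and Etv5 stood far above the rest; 4 of the 14 alternatives placed the list below the central 95%, but a level of 7 turned the median to 0.20 at percentile 79.7 and the mean lay at percentile 91.5. The heat shock list (median -0.19, percentile 31.7), p53 targets (0.16, percentile 88.9), the interferon list (-0.21, percentile 55.9) and the glycolysis and hypoxia list (-0.27, percentile 19.6) lay within the random lists. So did the S phase genes at -0.06 (percentile 59.9) and the mitosis genes at -0.03 (percentile 59.0, mean 0.07).

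Most markers of other cell types were under the level, although 8 of 15 trophectoderm markers and 10 of 17 germline genes reached it. Of 27 fibroblast markers on the array, 7 were measured at the level, all below 0, with Col5a1 at -2.15, Col1a1 at -1.71 and Vim at -0.15; the median was -0.45 at percentile 20.5. After centring on the median gene 2 of the 7 were above 0, and after centring on the hybridization controls 5 were, with a median of 0.35. Of 19 primitive endoderm markers, 6 were measured, with a median of -0.65 at percentile 9.12 and Col4a2 at -1.86 and Col4a1 at -1.34 lowest. The 8 measured trophectoderm markers had a median of -0.47 (percentile 31.6). That median was -0.085 (percentile 80.9) at a level of 4 and 0.16 (percentile 78.7) when probe sets were averaged. Of 15 neural markers, 5 were measured, with a median of -0.17 (percentile 51.1), Stmn2 at 1.27 and Tubb3 at -1.53. Of 13 mesendoderm markers 3 reached the level, of 16 blood and endothelial markers 2, and of 7 markers of the two-cell-like state 0. Those lists, the histone genes (2 of 6) and the mitochondrially encoded genes (1 gene, ND5, at 0.08) were too small to set against random lists.

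The control probe sets differed along the transcript. The 5' probe set of Actb, cytoplasmic beta-actin, was 1.76 higher in the hybridized sample, the middle one differed by -0.09 and the 3' one by -0.76. The same 3 values for Gapdh, the glycolytic enzyme, were 0.96, -0.47 and -0.85. For Tfrc, the transferrin receptor, they were 1.88, -0.08 and 1.38. Ordinary probe sets of Actb differed by -0.24 and -0.29. Centring on the hybridization controls turns each of these negative values positive except that of the 3' probe set of Gapdh. The 3 probe sets for 18S ribosomal RNA had a median difference of -1.38, which stays below 0 under that centring. All 18 probe sets for the bacterial and phage transcripts added at array hybridization were also lower, at differences from -1.22 to -0.15 with a median of -0.80.

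**Figure D3:**
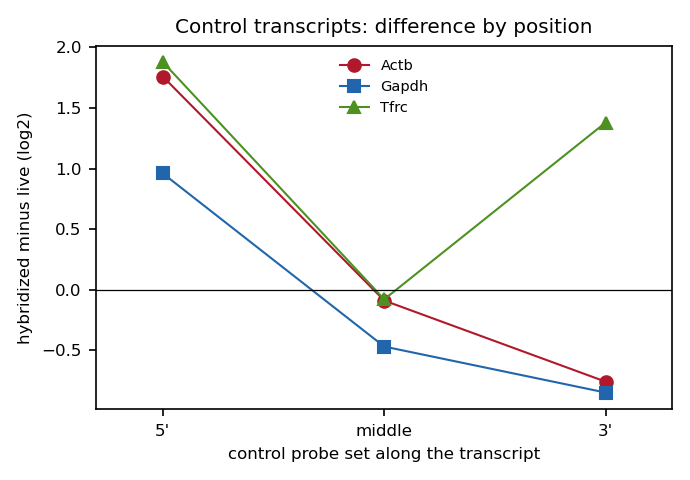
Log2 difference, hybridized minus live, at the 5', middle and 3' control probe sets of Actb, Gapdh and Tfrc, 1 array per group. The 5' probe sets were higher in the hybridized sample by 0.96 to 1.88, and the 3' probe sets of Actb and Gapdh were lower at -0.76 and -0.85 while that of Tfrc was higher at 1.38; the Actb 3' value turns positive when centred on the hybridization controls.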

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

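The test of the other immediate early genes and the germline lists lacking one gene each were chosen after the results were seen, as was Egr1.

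Control probe sets were not counted as genes, and only the 18 hybridization controls entered a comparison of genes, through the centring on them. Signal in control probe sets was at least 2-fold above the live sample in 3 cases, none of them a hybridization control. The 5' control of Actb was 1.76 higher, the 5' control of Tfrc 1.88 higher and the 3' control of Tfrc 1.38 higher. At least 2-fold lower were the 3 probe sets for 18S ribosomal RNA (-1.62, -1.38 and -1.20), 1 hybridization control for the bacterial gene bioB (-1.22) and the 3' control for pyruvate carboxylase (-1.12).

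The first pattern is the large number of genes at least 2-fold apart, 1727 of 7262. After the loess correction 1546 genes were still 2-fold apart, so a trend of the average difference with level is not the whole source. The test could hardly have come out otherwise. The trend was -0.51 to -0.06 by range of level, against SDs of 0.53 to 1.00. How far the spread itself depends on level is left untouched by this test. Of 545 2-fold genes with a second probe set, 36.1% repeated at 2-fold on it, under the 50% that the test required, and 23 were 2-fold apart in the opposite direction. An effect of single probe sets, such as their place on the transcript, would give a low share. So would measurement noise, since genes picked for a large difference on 1 probe set tend to differ less on another. The 50% limit cannot tell these apart. Base composition shared by neighbouring genes predicted that genes near each other differ alike, and the differences of measured genes 10 places apart along the chromosomes correlated with rho = 0.132, against at most 0.0319 in 1000 shuffles. Base composition itself was not measured and shared regulation or chromatin of neighbours would give the same sign, so this, like the difference between hybridized and live cells, stays open.

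The second pattern is the germline genes, with a median 1.06 higher in the hybridized sample. The list lay at percentile 99.97 before and after the loess correction. This decides nothing about a trend with level, because the random lists were already matched on level. As deposited the trend itself ran the other way: the median gene was below 0 in each range of level, from -0.51 to -0.06. That argues against level as the source of a median above 0 in the deposited values. With control centring the median gene was at 0.63 and the list's median at 1.855, so the sign for the median gene depends on the centring. Leaving out each of the 10 genes in turn gave a lowest percentile of 99.915 but decides nothing, since the middle values of 1.06 and 1.05 fix the median. An effect of single probe sets was not decided, because 1 gene had a second probe set at the level, 1.05 higher. A difference between hybridized and live cells is untested for lack of replicates and may be weighed only with more arrays.

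The third pattern is Fos and Egr1, 4.10 and 4.97 higher in the hybridized sample on a single probe set each. The smaller of their differences was 4.35 after the loess correction. That outcome was fixed beforehand, because the trend with level was small and below 0 as deposited, at -0.51 to -0.06 by range of level. A trend in that direction cannot raise these genes, which argues against it as their source in the deposited values. With control centring the median gene was at 0.63 and Fos at 4.90, so that direction holds only as deposited. A response of the whole immediate early class was not decided, since the other 18 measured members had a median difference of -0.375 (quartiles -0.70 and 0.11) as deposited and of 0.43 (quartiles 0.10 and 0.91) when centred on the hybridization controls. A response of a few members, with Gadd45a and one of the probe sets of Gadd45b, could remain, as could an effect of the single probe sets, and neither was tested.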

How the results depend on the processing

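Centring on the hybridization controls, leaving out only _x_at and _s_at probe sets, the repeat on a second probe set, short mRNAs without shared genes and germline lists lacking one gene each were chosen after the data were seen. No paired analysis was possible because each group has 1 sample, and no sample was left out for the same reason. As the threshold was moved, 3437 genes were apart at 1.5-fold (1268 higher, 2169 lower) and 200 at 4-fold (87 higher, 113 lower). Genes 2-fold lower numbered 713 at a level of 7 and 708 after loess, against 1115; the first setting compares fewer genes. Centring on the hybridization controls gave 2310 higher and 206 lower by construction, and requiring a repeat on a second probe set gave 197 (76 higher, 121 lower) among 2720 genes. The correlation of the arrays was 0.940 at a level of 4, 0.878 at 7, 0.979 with no limit, 0.910 without the suffixed probe sets, 0.915 with _a_at kept and 0.915 after loess. The agreement of probe sets was 0.313 with no limit on level. The number of lists apart was 4 without the suffixed probe sets, 3 with _a_at kept and 3 without matching on level, against 7, and 6 to 9 otherwise; the cause was not tested. Centring on the hybridization controls turned the medians of the 6 lower lists positive, at 0.16 for the stress response, 0.43 for ribosomal proteins, 0.47 for oxidative phosphorylation, 0.38 for membrane and secreted proteins, 0.53 for cytosolic proteins and 0.40 for short mRNAs, with their percentiles unchanged. Of 394 list values under alternatives, 364 kept their side, 17 of a list apart fell inside the random lists and 7 of other lists fell outside. These counts are partly fixed, since 2 of the centrings shift all genes alike and cannot move a percentile. The germline lists lacking a gene each, counted too, could hardly leave their side, because the middle values fix the median. Short mRNAs without ribosomal and respiration genes stayed apart at -0.41. Of 497 values for 55 named genes, 414 moved by less than the probe set spread of 0.73. That count is largely fixed by the settings. The level limits leave a gene's value unchanged, median centring shifts all genes alike by less than 0.73, and control centring shifts all by 0.80. Among genes at least 2-fold apart 1 changed sign, Ndufb9 at 0.50 without the suffixed probe sets (-1.39 with _a_at kept). Etv5, Rp2, Shmt2, Ndufv2, Ndufs7 and Cd151 were also under 2-fold without the suffixed probe sets. Of smaller differences, Esrrb turned to 0.41 with averaged probe sets, through a probe set under the level. Bola2 turned to 0.02 without the suffixed probe sets and Klf4 to 0.08 with median centring. Sox2 turned to 0.16 with median centring, 0.11 with loess and 0.15 with quantile normalization, and differences between -0.80 and 0 turned positive with control centring. The relation with transcript length was not run. The SD of the differences was 0.98 at means from 5 to under 7, 1.00 from 7 to under 9 and 0.53 from 11; the cause was not tested, and signal over background was not measured.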

Other observations

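The direction of pairs of 2-fold neighbours was a test chosen after the results were seen.

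Genes of cholesterol synthesis went in both directions. Fdps was 3.27 higher in the hybridized sample, Hsd17b7 1.10 and Cyp51, lanosterol demethylase, 1.05, whereas Mvd differed by -1.39, Lss by -0.96 and Pmvk by -0.83; the list's median over 18 genes was -0.29 at percentile 19.5 and its mean 0.05. Among 13 measured imprinted genes, Peg10, a retrotransposon-derived gene, read 8.22 against 4.11 and Impact was 1.09 higher, while Ndn differed by -1.10; the median was 0.12 at percentile 85.8, and with the mean in place of the median (0.41) the list stood above the random lists at percentile 98.8. Nuclear long noncoding RNAs had 11 of 14 members above 0 and a median of 0.21 at percentile 92.6 (98.5 with no limit on level), with Oip5os1 (1.49) and Snhg11 (1.03) highest and Neat1 (-0.89) and Malat1 (-0.24) lowest. The splicing factor list of 36 genes had a median of 0.10 at percentile 95.8, and of 0.42 at percentile 99.9 when all probe sets of a gene were averaged. The 37 long mRNAs had a median of -0.22 at percentile 24.3, but of 0.10 at percentile 81.6 when probe sets were averaged, and the 6 measured Wnt pathway targets one of 0.15 at percentile 83.9, with a mean of -0.32 and a median of -0.37 at percentile 42.2 at a level of 4. Peg10 and the other genes named in this paragraph outside the fixed rule were chosen after their values were seen.

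Neighbouring genes differed alike, less so at the largest distances. The rank correlation of differences over genes was 0.198 for adjacent measured genes, 0.176 at 2 places, 0.130 at 5, 0.132 at 10, 0.0871 at 20 and 0.0380 at 50, where the highest of 1000 shuffles was 0.0441. Among 439 adjacent pairs in which each gene was at least 2-fold apart, 76.5% had the same direction, against at most 63.1% in 1000 shuffles. For 421 such pairs 10 places apart the share was 66.3%, against at most 61.8%.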
